A study of Mus musculus with 8 samples.

How the data were processed

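The series holds 8 Affymetrix mouse genome 430 version 2 arrays, 1 per mouse, from germinal vesicle-stage oocytes of 4 wild-type and 4 Dicer knockout mice, with groups taken from the genotype label. Per the labels' protocols, 20 oocytes per mouse were used, RNA was isolated with the PicoPure kit, amplified linearly in 2 rounds and labelled with biotin. The deposited values are log2 signals per probe set, and the submitters' processing notes name RMA (which corrects background, normalises across arrays and summarises probes) and Partek, with versions not given in the sources used here. RMA compresses low signals, so fold changes of dim genes are lower than those of the RNA, and amplification of small samples favours transcript 3′ ends. The matrix had 45101 probe sets, 0 missing values and 0 columns of other samples. No detection calls were used here, so a dim gene has no stated background. The labels give each mouse as a separate sample, and no pair of arrays was identical.

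Probe sets were named from the platform annotation and looked up by gene identifier in the RefSeq gene table of assembly GRCm38.p6. Of 45037 probe sets that are not among the 64 controls, 34945 had 1 gene symbol, 932 had several and 9160 had none listed there, and 34741 of those with 1 symbol matched the gene table, with 0 symbols that needed updating. A gene was represented by its probe set with the highest mean over all 8 arrays, among probe sets with 1 symbol, which gave 18193 genes. No genome build is named for the arrays, so the gene table served for names, chromosomes and neighbours only, and no coordinates are printed.

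The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, knockout minus wild type, no covariates) on the deposited log2 values. Benjamini-Hochberg adjustment was made over all 45037 probe sets, and adjusted p under 0.05 counted as passing. Words such as rose and fell refer to this test, and every adjusted p of a gene is limma's. Fold changes are 2 to the power of the log2 difference of group means. Errors are SDs over 4 arrays per group or the moderated SE of a difference. On simulated data with the spread of these arrays, 200 of 45037 probe sets were changed, and the fit recovered 39.4% of 66 changed by 0.5 log2, 89.9% of 69 changed by 1 and 100% of 65 changed by 2, with 7 false among 160 calls. The simulated noise was independent between probe sets, and far fewer of them changed than passed in the real data. These rates may therefore not carry over.

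The 21 gene lists were tested with camera (limma) on the representative probe sets, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. Lists needed at least 5 measured members. They covered small RNA machinery, genes reported to match oocyte siRNAs, oocyte genes, cumulus and granulosa cells, other ovarian and blood cells, meiotic cell cycle, spindle and motors, mRNA storage and decay, chromatin, interferon response, p53 and apoptosis, let-7 targets, stress, ribosomal proteins, oxidative phosphorylation, proteasome, tubulins, DNA replication, Zfp-named genes, the 2-cell burst and metabolism. Genes were named in the text by a rule. It took every Dicer1 probe set, and the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups, leaving out predicted and clone names. In each list it took the 2 members with the lowest p in each direction, and every measured siRNA-matched gene. Further genes named beside a count complete it and were chosen after their values were seen.

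The groups, the model, the lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were a filter on dim probe sets, quantile, median and cyclic loess scaling, other variance models, array weights, the first number of the title code as a random block, the mean of a gene's probe sets, leaving out probe sets with suffixes for shared sequence, and leaving out each array. A test of microRNA seed matches in 3′ UTRs was planned and not run, because no UTR sequences were used here. Lists in the closing section were compared with 10000 random lists matched on level, and the margin of 1 SD of the random lists below their median, which a result had to pass to count against an idea, was set after the predictions had been written. Single values were compared with exact two-sided permutation tests over 70 arrangements, whose smallest p is 0.0286.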

Results

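Transcript levels were measured in fully grown mouse oocytes that still held an intact germinal vesicle, the large nucleus of the oocyte before meiosis resumes. The oocytes came from females of a mixed inbred background given equine chorionic gonadotropin, a hormone that makes ovarian follicles grow, and were stripped of cumulus cells by pipetting. RNA of 20 oocytes per mouse was amplified in 2 rounds and hybridised to 1 Affymetrix mouse genome array per mouse, with 4 wild-type mice and 4 mice labelled Dicer knockout. Each array gave log2 signals for 45101 probe sets. Array medians lay between 6.35 and 6.43, and the number of arrays limits the precision. Pairs of arrays correlated at r = 0.9915 to 0.9947 across probe sets within the groups and at 0.9797 to 0.9865 between them, a correlation across probe sets, which are not independent replicates. The first principal component held 55.6% of the variance and separated the groups.

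The comparison asks which maternal transcripts differ when the oocyte lacks Dicer, the ribonuclease that cuts microRNAs and short interfering RNAs from their precursors. Dicer1 signal was higher on the arrays labelled Dicer knockout, in both of its probe sets. The brighter one read 13.13 ± 0.125 (SD, n = 4) in wild type and 14.32 ± 0.044 (n = 4) in knockout, a difference of 1.19 ± 0.0789 (SE) on the log2 scale or 2.28-fold (adjusted p = 2.12e-05). The other read 11.62 ± 0.166 and 12.31 ± 0.131, 1.61-fold higher (adjusted p = 0.0017). The exact two-sided permutation p was 0.0286 for each, the smallest that 4 against 4 arrays can give. The labels do not say which exons were deleted, so neither probe set checks the genotype.

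Of 18193 genes tested, 1488 were higher and 2330 lower in knockout oocytes, together 21% of the genes. At least 2-fold changes were found in 430 genes that rose and 371 that fell. In 93.8% of the genes past the threshold, all 4 knockout values lay on one side of all 4 wild-type values. Among single probe sets, 3072 rose and 4192 fell. In 115 genes, different probe sets passed the threshold in opposite directions, which includes Ccdc82 below. Of 2154 genes past the threshold with more than 1 probe set, 968 had another probe set that passed in the same direction. In 95 of them another passed in the opposite direction.

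**Figure D1:**
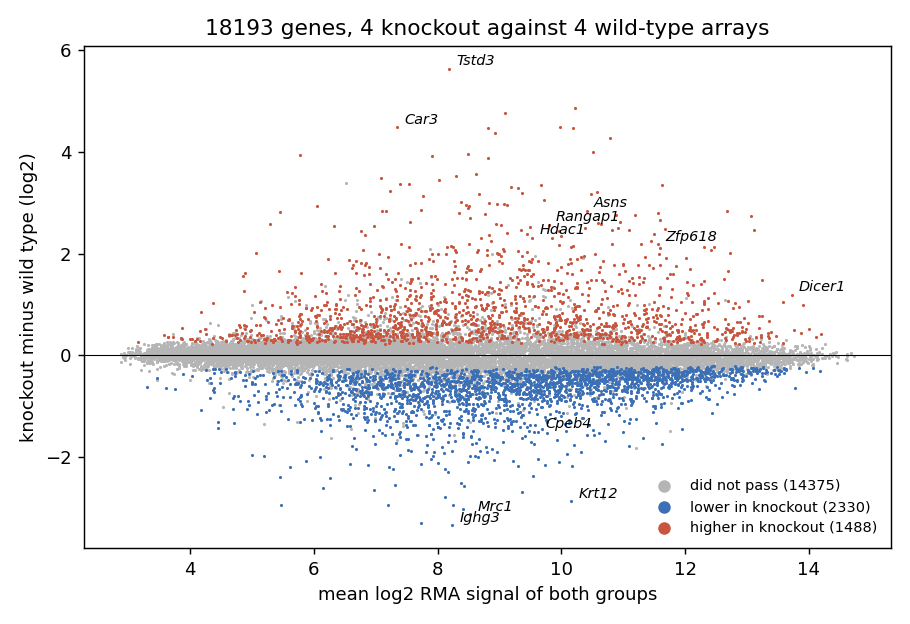
Knockout minus wild type on the log2 scale (vertical) against the mean log2 RMA signal of both groups (horizontal) for 18193 genes, 1 point per gene. The 1488 genes that rose reach 5.64, and the 2330 that fell reach -3.35.

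The 8 largest rises lay between 19.3-fold and 49.8-fold. Tstd3, a gene of the thiosulfate sulfurtransferase family, rose from 5.37 ± 1.63 to 11.01 ± 0.12 (SD, n = 4 and 4), a log2 change of 5.64 ± 0.652 (SE). B4galnt2, which makes a terminal sugar on glycoproteins, rose from 7.78 ± 1.05 to 12.65 ± 0.0465, or 29.3-fold, and 8.59-fold and 5.60-fold in 2 of its 3 other probe sets. Car3, a carbonic anhydrase, rose from 5.10 ± 0.6 to 9.59 ± 0.228, or 22.4-fold, and 2.25-fold in a probe set brighter in wild type (6.35 to 7.52), while its 2 others did not pass. Mcf2 (27.4-fold), Vav3 (19.3-fold), Saxo1 (22.5-fold), the opposite-strand transcript Prkag2os1 (22.2-fold) and Ccdc82 (20.8-fold) completed the 8 largest rises. Of 3 Ccdc82 probe sets, 1 rose and 1 fell. In all 8 genes wild-type array 1 was the highest wild-type array, by 0.99 to 3.11 log2 over the mean of the other wild-type arrays. Without wild-type array 1 the 8 log2 changes lay between 4.73 and 6.41 in place of 4.27 to 5.64, and that of Tstd3 moved the most, to 6.41 or 85-fold.

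Ighg3, an immunoglobulin heavy chain constant region, fell from 9.91 ± 0.111 to 6.56 ± 0.133, a log2 change of -3.35 ± 0.0905 (SE, n = 4 and 4). Mrc1, the macrophage mannose receptor, fell from 10.09 ± 0.284 to 6.96 ± 0.478, a change of -3.13. Plek, a substrate of protein kinase C in platelets, fell from 9.72 ± 0.407 to 6.78 ± 0.0965, and Cd200, a membrane glycoprotein, from 9.91 ± 0.431 to 6.90 ± 0.406. Defb41 (a beta-defensin, -3.31), Elk3 (an ETS factor, -2.94), Krt12 (a keratin, -2.87) and Cobl (an actin nucleator, -2.79) completed the 8. For Elk3, 1 of 4 probe sets passed the threshold, and for Cobl 1 of 2. For Ighg3, 2 of 4 passed, the dimmer of them with a log2 change of -0.80. The remaining Ighg3 probe sets read 3.20 and 3.34 in wild type and 3.29 and 3.33 in knockout. Whether the bright Ighg3 signal comes from that transcript was not tested. All 16 genes with the largest rises and falls passed in limma with adjusted p of 0.00186 or less, and none lost the call when single arrays were left out.

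**Figure D2:**
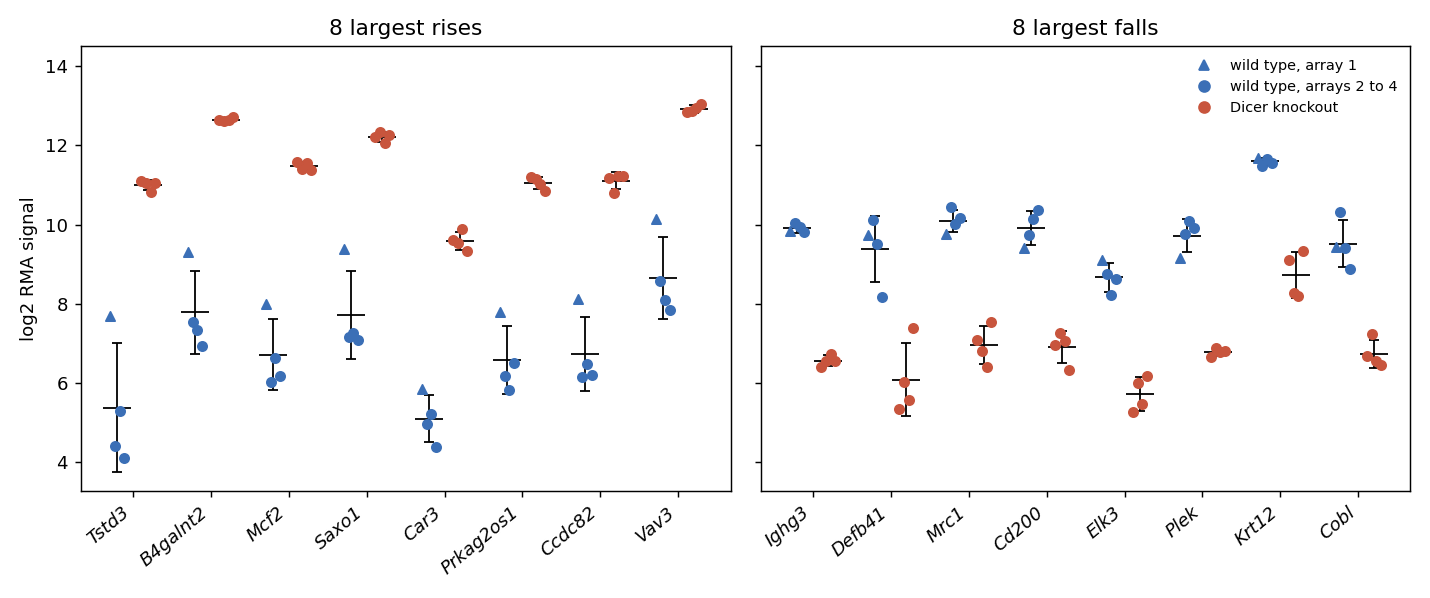
Log2 RMA signal (vertical) of the 8 genes with the largest rises and the 8 with the largest falls (horizontal), 1 point per array, with mean and SD of 4 arrays per group. Triangles mark wild-type array 1, the highest wild-type array in all 8 genes that rose most.

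Genes reported to match short interfering RNAs of mouse oocytes rose, 5 of the 6 measured. Rangap1, the GTPase activator of Ran, rose from 8.52 ± 0.393 to 11.08 ± 0.108 (SD, n = 4 and 4), or 5.92-fold (adjusted p = 2.29e-05). Hdac1, a histone deacetylase, rose from 8.37 ± 0.323 to 10.68 ± 0.178, or 4.96-fold, and Ppp4r1, a regulatory subunit of protein phosphatase 4, from 9.73 ± 0.568 to 11.92 ± 0.13, or 4.55-fold. Kif4, a chromosome-bound kinesin, and Elob, a subunit of elongin, rose 1.65-fold and 1.66-fold. Pdzd11 read 11.48 ± 0.187 and 11.85 ± 0.181 (adjusted p = 0.0642). Without wild-type array 3 it passed (log2 difference 0.46, adjusted p = 0.0221), and 2 of its 3 probe sets passed with all arrays. All 6 passed when adjusted over the list alone. Relative to other genes the list was higher with camera's preset correlation (adjusted p = 7.99e-06), and adjusted p was 0.278 with an estimated correlation. The list was written from memory of reports on Dicer-deficient oocytes, so it is not independent evidence of its direction. Optn was not analysed here.

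**Figure D3:**
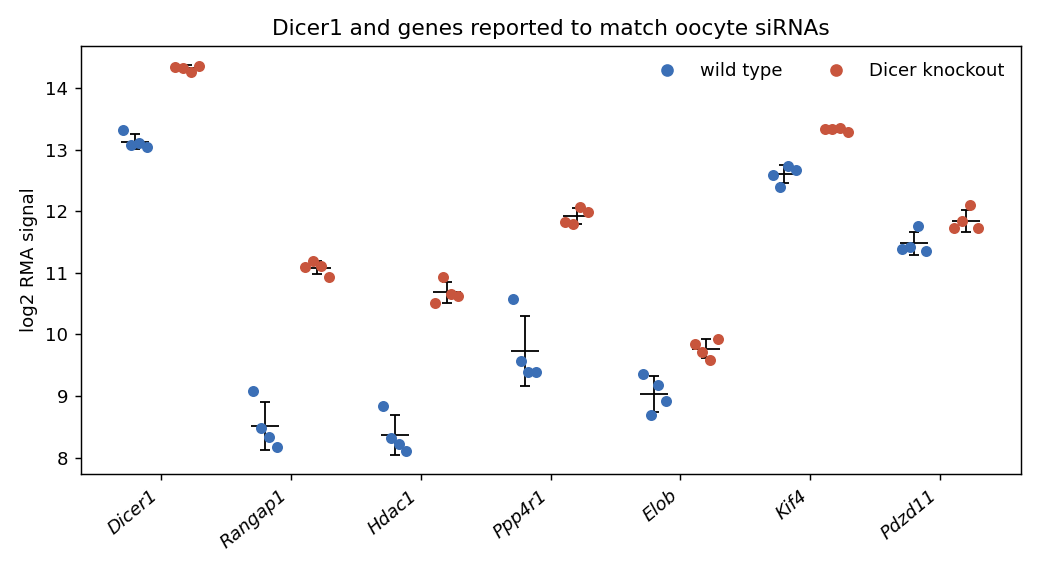
Log2 RMA signal (vertical) of Dicer1 and of 6 genes reported to match oocyte short interfering RNAs (horizontal), 1 point per array, with mean and SD of 4 arrays per group. Groups were apart in every gene but Pdzd11, where wild-type and knockout arrays overlapped.

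Of 77 genes of oxidative phosphorylation, which encode the mitochondrial respiratory chain and ATP synthase, 19 fell and 0 rose (25 and 0 adjusted over the list alone). Cox7a2, of complex IV, fell from 13.00 ± 0.16 to 12.04 ± 0.216 (log2 -0.96, adjusted p = 0.000719), and Uqcrfs1, the Rieske protein of complex III, from 11.55 ± 0.106 to 11.02 ± 0.0562 (log2 -0.54, adjusted p = 0.00125). The list median was -0.16. The list was lower than other genes with the preset correlation (adjusted p = 2.34e-05), and adjusted p was 0.772 with an estimated correlation of 0.303. Of 48 ribosomal protein genes, 2 fell (Rpl38, log2 -0.54, and Rps25, log2 -0.38) and 0 rose, with 1 and 0 adjusted over the list alone, and the list did not pass (adjusted p = 0.0628). In the proteasome list of 39 genes, Psmb5 rose and Psmc1 and Psmb11 fell, and adjusted over the list alone 0 rose and 1 fell.

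Of 23 cumulus and granulosa cell markers, genes of the somatic cells that surround the oocyte, 9 fell and 0 rose (10 and 0 adjusted over the list alone), although the oocytes had been stripped by pipetting. Nr5a2, a nuclear receptor, fell from 10.67 ± 0.0664 to 10.24 ± 0.153 (log2 -0.44, adjusted p = 0.00863), and Greb1 from 9.54 ± 0.165 to 8.86 ± 0.281 (log2 -0.68). Chosen after their values were seen, the other genes that fell were Cyp11a1 (log2 -1.57), Inhbb, Fst, Inha, Npr2, Hsd17b1 and Fshr (log2 -0.50), and Amh, Kitl, Foxl2 and Star did not pass. As a list the markers missed the threshold (adjusted p = 0.0628). They passed without wild-type array 2 (adjusted p = 0.0219), wild-type array 3 (0.0392) or knockout array 4 (0.0171), and the ribosomal list passed without wild-type array 2 (0.00806), wild-type array 4 (0.0417), knockout array 1 (0.0159) or knockout array 4 (0.0115). Of 20 markers of theca, stroma, vessel and blood cells, Cd68, a macrophage lysosomal protein, rose (2.24-fold), and the endothelial receptors Tek (log2 -0.78) and Kdr (log2 -0.54) fell, with 2 and 2 adjusted over the list alone.

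Genes of the spindle, kinetochore and microtubule motors changed in both directions, 12 of 63 higher and 9 lower (12 and 10 adjusted over the list alone). Kifc1, a minus-end directed kinesin, rose from 10.74 ± 0.285 to 12.65 ± 0.108, or 3.77-fold, while Kif11, the kinesin that slides spindle microtubules apart, fell from 10.78 ± 0.0872 to 10.05 ± 0.0426 (log2 -0.73) and Kif18a fell by 0.61 in log2. Rangap1 is in this list too. Of 40 meiotic cell cycle genes, 5 rose and 8 fell (6 and 11 adjusted over the list alone). Stag3, a meiotic cohesin subunit, rose 2.37-fold and Map2k1 1.28-fold, while Sgo2a, which protects centromeric cohesin, fell from 11.20 ± 0.118 to 10.35 ± 0.137 (log2 -0.85) and Pde3a, the oocyte phosphodiesterase that lowers cAMP, fell by 0.79. Of 33 tubulin and chaperonin genes, Tbcd, a tubulin folding cofactor, rose 3.05-fold, Tubb5 1.36-fold, and Tubb6, named after its values were seen, was the remaining gene that rose. Cct8 fell (log2 -0.27), and the counts were 3 and 1 on both adjustments. None of these lists stood apart from other genes.

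**Figure D4:**
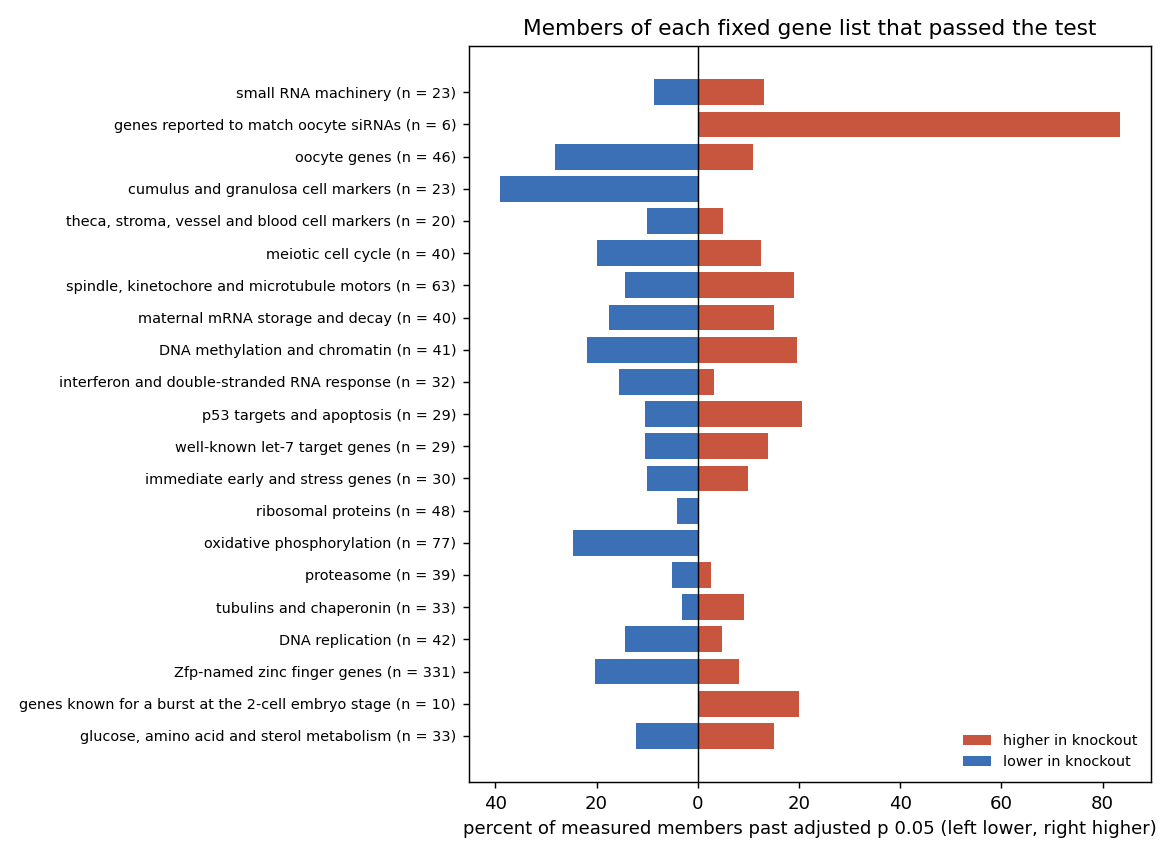
Percent of measured members (horizontal) of 21 fixed gene lists (vertical) that were higher (right) or lower (left) in knockout at adjusted p under 0.05. Most lists held members of both directions, while 5 of 6 genes reported to match oocyte siRNAs rose and 19 of 77 oxidative phosphorylation genes fell.

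Oocyte genes fell more often than they rose, 13 against 5 of 46 (15 and 5 adjusted over the list alone), and the list did not differ from other genes (adjusted p = 0.248). Mos, the kinase that holds eggs at metaphase, fell from 13.63 ± 0.0514 to 13.27 ± 0.0851 (log2 -0.36), and Fbxw16 fell by 0.64. Sohlh2, a transcription factor of early oocytes, rose 2.25-fold and Oog4 1.36-fold. In maternal mRNA storage and decay, 6 of 40 genes rose and 7 fell (7 and 8 adjusted over the list alone). Dcp2, which removes the mRNA cap, rose from 9.86 ± 0.727 to 12.32 ± 0.104, or 5.52-fold, in 1 of its 2 probe sets, while the other did not pass (log2 -0.31, adjusted p = 0.2). Parn, a poly(A) ribonuclease, rose 1.22-fold. Cpeb4, which binds polyadenylation elements, fell from 10.38 ± 0.279 to 8.88 ± 0.393 (log2 -1.51), and Cnot6, a deadenylase, by 0.51. In small RNA machinery, Dicer1, Ddx6 (1.69-fold) and Piwil2, named after its values were seen, of 23 genes rose, and Pld6 (log2 -0.39) and Tdrkh (log2 -0.31) fell, with 3 and 4 adjusted over the list alone. Argonaute genes did not pass.

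DNA methylation and chromatin genes went both ways, 8 of 41 higher and 9 lower (8 and 12 adjusted over the list alone). Besides Hdac1, the histone methyltransferase Ehmt2 rose 1.82-fold (7.07 ± 0.18 to 7.93 ± 0.0803) in 1 of its 2 probe sets. The other Ehmt2 probe set did not pass (log2 0.05, adjusted p = 0.759). The retinoblastoma relatives Rbl1 and Rbl2 fell (log2 -0.61 and -0.66). Of 331 Zfp-named zinc finger genes, 67 fell and 27 rose (85 and 42 adjusted over the list alone). Zfp618 rose from 10.48 ± 0.137 to 12.66 ± 0.161, or 4.54-fold, and Zfp930 3.47-fold, while Zfp41 and Zfp810 fell by 1.30 and 1.24. DNA replication genes fell in 6 and rose in 2 of 42 cases on both adjustments. Gins2 rose 2.08-fold and Pola1 1.72-fold, and Rfc4 and Gmnn fell by 0.80 and 0.54. Among 10 genes known for a burst in the 2-cell embryo, the ubiquitin protease gene Usp17la rose from 5.86 ± 0.243 to 9.22 ± 0.516, or 10.3-fold, Tcstv1 rose 1.62-fold, and 0 fell (3 and 1 adjusted over the list alone).

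Of 32 interferon and double-stranded RNA response genes, 1 rose and 5 fell on both adjustments. Oas3 rose 2.50-fold, while Ddx58, the sensor RIG-I, fell from 11.27 ± 0.148 to 10.34 ± 0.197 (log2 -0.93) and Mx1 by 0.50. Of 29 p53 targets and apoptosis genes, 6 rose and 3 fell on both adjustments. Zmat3 rose 2.74-fold and Gadd45a 1.94-fold, while Apaf1, the scaffold of the apoptosome, fell from 8.89 ± 0.0813 to 7.48 ± 0.149 (log2 -1.41) and Trp73 by 1.01. Of 29 well-known let-7 targets, 4 rose and 3 fell (4 and 4 adjusted over the list alone), the targeted gene Dicer1 being 1 of those that rose, with Hmga2 2.54-fold higher (10.92 ± 0.214 to 12.26 ± 0.123), Lin28b lower (log2 -0.98) and Igf1r lower (log2 -0.86). Immediate early and stress genes rose in 3 and fell in 3 of 30 cases (5 and 4 adjusted over the list alone). Asns, asparagine synthetase, rose from 8.99 ± 0.934 to 11.83 ± 0.383, or 7.15-fold, and Hspa1a 2.29-fold, while the endoplasmic reticulum chaperone Hsp90b1 fell by 0.90 and Fosb by 0.81. In glucose, amino acid and sterol metabolism, 5 of 33 genes rose and 4 fell (6 and 5 adjusted over the list alone). Shmt2, of mitochondrial folate metabolism, rose 2.06-fold and Hk2 1.72-fold, while Sqle and Slc7a6 fell by 0.46 and 0.56.

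Of the 21 lists, the siRNA-matched genes and oxidative phosphorylation passed camera with the preset correlation, and 0 passed with an estimated correlation. The median and the mean change differed in sign in the small RNA, mRNA storage, chromatin and let-7 lists. Of 86 named genes past the threshold, 77 kept the call whichever array was left out. Of the 45 with more than 1 probe set, all probe sets passed in the same direction in 20, and in 15 some probe set had the opposite sign (Car3, Ccdc82, Ighg3, Cobl, Ddx6, Nr5a2, Pde3a, Kif11, Kif18a, Dcp2, Rbl1, Ddx58, Igf1r, Cct8 and Pola1). The calls of Tdrkh, Pld6, Rps25, Psmb5, Psmb11, Cct8, Slc7a6, Fosb and Tcstv1 ended without some single arrays, at adjusted p up to 0.118. Leaving out wild-type array 2 ended 9 of these calls, wild-type array 4 ended 8, knockout array 2 ended 7, knockout arrays 3 and 4 ended 6 each, wild-type array 1 ended 4, and wild-type array 3 and knockout array 1 ended 3 each.

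RNA quality was compared by the control probe sets at both ends of the actin and Gapdh transcripts. The 3′ minus 5′ log2 signal of actin was 2.32 ± 0.274 in wild type and 2.14 ± 0.145 in knockout (SD, n = 4 and 4, exact two-sided permutation p = 0.257). That of Gapdh was 2.96 ± 0.0817 and 2.82 ± 0.153 (exact two-sided permutation p = 0.143, both 0.257 after Benjamini-Hochberg adjustment).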

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

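The tests of a mixed sample and of a swapped label were chosen after the values of wild-type array 1 were seen.

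In each group of 4 arrays, single arrays far from the other 3 were looked for in 220 sets of values (named genes, list means and quality measures), by the gap to the nearest array relative to the whole range. Such arrays were found in 15 sets, where chance alone gives about 11. In 3 genes the high array was wild-type array 1. Saxo1 read 9.39 there and 7.09 to 7.27 on the other wild-type arrays, Ccdc82 read 8.12 against 6.14 to 6.48, and Ppp4r1 read 10.57 against 9.39 to 9.57.

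Wild-type array 1 lay part-way to the knockout arrays in genes that rose. In a fit without it, made and adjusted on the representative probe sets alone, 496 genes that passed were at least 2-fold higher in knockout. In 374 of them (75.4%) array 1 exceeded all 3 other wild-type arrays. The same share was 10.2% to 14.5% for the other wild-type arrays. The matching share, of genes lying beyond the other knockout arrays towards wild type, was at most 42.3% for a knockout array. A swapped label is argued against, since array 1 correlated with the other wild-type arrays more than with the knockout arrays, by 0.00739 in mean r (lowest r 0.9915 against highest 0.9865). For RNA of knockout oocytes mixed into the sample, a single admixed fraction gave 15% for genes that rose and 15.1% for genes that fell (ratio 1.01), but wild-type array 3 gave 20% for genes that fell. Against it, the median fraction dropped steadily with the size of the rise, from 25.6% at 1.41-fold to 2-fold over 19.2% and 14% to 9.99% above 8-fold (ratio 1.92 from the 2-fold to the 8-fold step), where 1 admixture gives 1 fraction, while the share on the log2 scale stayed at 28.4% to 33%. A mixed sample stays open, because the ratio of 1.92 lay between the margins set for and against it (1.5 and 2). The ratio of 1.01 met the first margin. For genes that fell, however, wild-type arrays 2, 3 and 4 gave 0%, 20% and 9.62%. The 15.1% of array 1 thus did not stand apart, and the ratio of 1.01 decides nothing. The interquartile ranges of the fractions, a spread between genes, overlapped (7.72% to 39.3% at 2-fold to 4-fold, 6.99% to 13.7% above 8-fold). The title code of array 1 shares its first number with knockout array 2, and whether this mouse was related to it, heterozygous or partly recombined was not tested, nor was any other biological explanation.

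The remaining values far from their group were these. Pdzd11 read 11.75 on wild-type array 3 against 11.35 to 11.41. Parn read 11.47 on wild-type array 3 against 11.54 to 11.55. Sqle read 10.80 on wild-type array 3 against 10.51 to 10.54. The mean of the let-7 targets was 8.67 on wild-type array 3 against 8.76 to 8.78. Ccdc82 read 10.80 on knockout array 2 against 11.17 to 11.24. Asns read 12.40 on knockout array 2 against 11.61 to 11.69. Cnot6 read 10.34 on knockout array 3 against 10.22 to 10.23. Tbcd read 12.40 on knockout array 3 against 12.66 to 12.69. Hk2 read 8.89 on knockout array 3 against 9.28 to 9.33. Kif11 read 10.11 on knockout array 4 against 10.02 to 10.03. Ehmt2 read 8.05 on knockout array 4 against 7.88 to 7.90. Fosb read 4.81 on knockout array 4 against 5.49 to 5.62.

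Control probe sets stayed out of the gene comparison, and the 3 for Gapdh, a glycolytic enzyme, carried a difference between the groups. The 3′ probe set read 11.88 ± 0.242 in wild type and 13.18 ± 0.0896 in knockout (SD, n = 4 and 4), a log2 difference of 1.30. The middle and 5′ probe sets differed by 1.55 and 1.44, and in all 3 every knockout array exceeded every wild-type array. Gapdh had no other probe set among the genes tested. The 3′ control probe set of the transferrin receptor was higher by 0.23 in log2. Of 45 bacterial and phage controls, 12 passed when adjusted over the controls, all 12 higher in knockout, by 0.15 to 0.30 in log2, a shift between the groups in RNA that does not come from oocytes. All BioB, BioC, BioD and Cre probe sets among them were higher in knockout, by 0.03 to 0.30, whether they passed or not. The mean changes of the oxidative phosphorylation (-0.21) and ribosomal (-0.12) lists are of similar size and opposite sign. Whether this shift affects gene changes was not tested.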

How the results depend on the processing

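Covariates for the cumulus markers and for the component shared within groups were chosen after the results were seen, all other alternatives before. Counts of genes that rose and fell, overall and at 2-fold, stayed within 1.5 times of the reported counts under every alternative but the cumulus covariate. Scaling gave 1285 to 1745 genes higher and 1864 to 2530 lower, with 33.7% to 48.4% of calls higher, and moved the median of all genes by less than 0.1. Without single arrays, 1146 to 1398 genes rose and 1765 to 2091 fell, and without wild-type array 1, 1237 of the genes that rose and 1849 of those that fell kept their calls.

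The mean of the cumulus markers as a covariate, which itself differed between the groups and so takes up part of the comparison, left 669 genes higher and 586 lower (53.3% higher), and 1289 probe sets higher and 1010 lower. It left 1 list past the threshold, ended the oxidative phosphorylation call (adjusted p = 0.348) and ended 33 of 86 calls of named genes. Whether this reflects cumulus RNA or the overlap with genotype was not tested. The 2 lists that passed became 0 with an estimated correlation (siRNA-matched genes 0.278, oxidative phosphorylation 0.772) and 9 with fry, which does not compare a list with other genes. The number was 2 to 4 without single arrays, with 4 without wild-type array 2 or knockout array 4. It was 3 with the mean of probe sets and with the within-group component as a covariate, where ribosomal proteins passed too (adjusted p = 0.0426 and 0.0357). The cause was not tested. In the other alternatives both lists passed in the same direction.

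Dicer1 was higher in both probe sets under all alternatives run on it. No named gene reversed. Of 86 named genes past the threshold, 76 kept the call under all alternatives chosen beforehand. The title code's first number, whose meaning the labels do not give, is shared by 2 pairs of arrays across the groups, whose deviations correlated at -0.28 and 0.125. Within a group, wild-type arrays 3 and 4 share the first number 28. They lay on the same side of the first within-group component (-0.4 and -0.258), and whether these mice were related was not tested. As a random block the first number gave 1462 genes higher and 2317 lower and changed no list call. Actin and Gapdh 3′ minus 5′ differences were -0.21 and -0.16 after quantile scaling and again did not pass. The seed match test and its alternatives were not run. Signal over background was not given per probe set, so small changes of dim genes are the least certain.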

Other observations

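The lists of somatic genes, the oxidative phosphorylation tests, the chromosome test and the test near Dicer1 were chosen after the results were seen, while the tests of other splits, of pseudogene and antisense partners and of further Atf4 targets were written before their results were seen.

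Several genes of the amino acid response rose in knockout oocytes. Asns, Psat1 (serine synthesis, 3.53-fold), Shmt2, the cationic amino acid transporter Slc7a3 (from 5.94 ± 0.933 to 9.86 ± 0.349, SD, n = 4 and 4), the hormone Fgf21 (from 6.88 ± 1.49 to 10.76 ± 0.673) and Sesn2 (from 7.90 ± 0.282 to 9.08 ± 0.54) were noticed first, because they rose. Atf4 is the transcription factor that raises such genes when amino acids are short. Atf4 itself, Ddit3, Trib3 and Chac1 are in the stress list, where 3 of 30 genes rose. Asns and Hspa1a were among those 3, so most of Atf4, Ddit3, Trib3 and Chac1 did not rise. Of 30 further known Atf4 targets, whose values had not been looked at, 14 rose, 1 fell and 15 did not pass. Vldlr rose by 1.53 in log2, Stc2 by 1.21, the alanyl-tRNA synthetase gene Aars by 0.88, Atf5 by 0.87, Cebpb by 0.56 and the transporter chain Slc3a2 by 0.54. Slc7a11, a cystine transporter, was the exception and fell by 0.78. The list median of 0.31 exceeded all of 10000 random lists matched on signal level (percentile 100, random median -0.06). Random lists do not carry the correlation between members of a list, and the mice do not enter as replicates, so the percentile can overstate the evidence. A candidate explanation is an active amino acid response in these oocytes, as a hypothesis, since no protein or amino acid was measured.

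Arrays of both groups split on a shared component whose top genes were enriched on chromosome 2. Within groups, 31.6% of the spread lay on 1 component, and 27% of the 100 genes with the largest loadings lie on chromosome 2 of GRCm38.p6, which holds 7.76% of measured genes (Fisher's exact test p = 6.27e-09, 4.65e-07 adjusted over 120 component and chromosome pairs, of which 8 passed). Chromosome 8 passed on the same component (13% of top genes, 5.17% of measured genes, adjusted p = 0.0336). Bfsp1 read 10.53 to 11.67 on wild-type arrays 3 and 4 and knockout arrays 2 and 3, and 5.89 to 6.72 on the other 4 arrays. Zswim1 and Stk4, other chromosome 2 genes, split the same 8 arrays the opposite way, while Fgf7 (8.35 on knockout array 3), Tmem87a (11.12 on wild-type array 2) and Pla2g4e did not follow that split. This may come from a stretch of chromosome 2 that differs between the parental strains and was passed on to some mice of each group, although the 27 genes lie all along the chromosome (ranks 9 to 1356 of 1399 measured genes, median 976). The third component loaded on chromosomes 7 and 8 (27% and 20% of top genes). With the first component as a covariate, chosen after it was seen, 1836 genes rose and 2706 fell.

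Of 23 cumulus and granulosa markers 9 fell, and the list as a whole did not pass. The 9 varied together within groups (mean pairwise r 0.492 across arrays, percentile 100 of 10000 random lists of fallen genes, whose median was 0.02), which is consistent with a varying remnant of cumulus cells. Genes abundant in somatic cells had a median log2 change of -0.066, with 2 of 21 lower (Gja1 and Fn1) and Lgals1 higher. The median of these genes on each array, another measure, had an SE of the group difference of 0.0811 (exact two-sided permutation p = 0.0571). Cdh2 had the largest negative difference (log2 -1.14, adjusted p = 0.0649) and did not pass. Any of these genes may be expressed in oocytes too. Fewer attached cells and lower transcript levels per cell cannot be told apart. The median log2 change of the somatic genes was negative, but reached neither the fall set for fewer attached cells nor the rise set against it.

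The mean over 77 oxidative phosphorylation genes, of which 19 passed, differed by -0.21 in log2, and that over ribosomal protein genes, which did not pass, by -0.12 (exact permutation p = 0.143). The list did not pass with an estimated correlation (adjusted p = 0.772) or with the cumulus marker mean as a covariate, chosen after the results were seen (adjusted p = 0.348). After the ribosomal mean of each array was subtracted, all 4 knockout arrays still lay below all 4 wild-type arrays (exact permutation p = 0.0286, the smallest possible), although knockout array 3 (-0.113) and wild-type array 4 (-0.112) nearly met. This argues against a shift shared with ribosomal protein genes as the whole cause. Whether the shift between the groups in bacterial and phage controls, opposite in sign, bears on the list was not tested. An effect of the genotype stays open and untested. A difference in RNA degradation stays open too, since the smaller exact permutation p of the 3′ minus 5′ differences was 0.143. Their 95% intervals, knockout minus wild type, ran from -0.56 to 0.198 for actin and from -0.35 to 0.0777 for Gapdh. Both differences (-0.181 and -0.134) were negative, a smaller 3′ excess in knockout.

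No other division of the 8 arrays into 4 and 4 gave as many changed probe sets as the genotype. Of 35 splits into 4 and 4, 1 gave as many as the 7264 of the genotype split, which is that split itself, and the highest of the others gave 21. By chance the genotype split would rank first in 1 of 35 cases, so chance is argued against and not excluded. Each other split mixes the groups, which adds their difference to the spread and lowers its count. Genotype and a technical difference between the groups cannot be told apart by this test.

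Strain DNA linked to the targeted gene was tested on the neighbours of Dicer1 on chromosome 12. Of the 40 measured genes on each side, 80 in all, 13 passed the threshold (16.2%, 95% exact binomial interval 8.95% to 26.2%), against 21.1% of other genes (Fisher's exact test p = 0.337), so an excess was not found and a small one not excluded.

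That partner transcripts mark the genes that rose was not shown. Genes with a named pseudogene copy, a source of oocyte siRNAs, rose in 20 and fell in 29 of 263 cases (7.6% rose, percentile 16.7 of 10000 random lists matched on level, median 9.13%). Hdac1, Kif4 and Rab11b (log2 1.69) were among those that rose. Genes with a named opposite-strand transcript rose in 20 and fell in 24 of 195 cases (10.3% rose, percentile 74.5, median 8.72%), with Saxo1 and Nrg3 (log2 2.95) among those that rose. By the rule written beforehand, a share at or below the random median, the pseudogene result counted against the idea, and the antisense result decided nothing. Both shares lay within 1 SD of the random median or above it, a margin set after the predictions were written, under which both stay undecided. Names cover few of the pseudogenes and antisense transcripts that exist.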
